A study of Homo sapiens with 4 samples.

How the data were processed

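Total RNA was sequenced from 4 libraries of K562 cells, 2 transduced with a non-specific CRISPR lentivirus (control) and 2 with one against DROSHA (knockdown), at passages 25 to 30 after selection with puromycin at 2.5 ng/μl, per the labels. Libraries were made with the TruSeq Stranded Total RNA kit, per the labels' protocols. That kind of library covers nuclear and non-polyadenylated RNA as well as mRNA, and it does not capture mature microRNAs. Groups were taken from the sample labels.

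The authors deposited 1 table of their own comparison. It gives for each gene a mean normalised read count (a signal over all 4 libraries), a log2 fold change and an adjusted p-value, per the file headers. The submitters' processing notes name Bowtie2 2.3.4.1, STAR 2.6.0a, DESeq2 1.24.0 and the genome build hg38. The gene counter, its strand setting and the annotation release are not given in the sources used here. Genes that overlap, antisense genes included, can therefore share reads. A second log2 value deposited by the authors, for 8636 protein-coding genes, carries a header that speaks of the 5′ UTR and coding sequence. Its assay and direction are not stated, and it was not used here.

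The header does not state the direction of the log2 fold change. It was read as knockdown over control because DROSHA is negative, and every direction in the text rests on that reading. The table has 0 columns of values for single libraries. The tests chosen before the data were examined (edgeR on counts or limma on normalised values, and camera on the values of each library) need such columns, so the authors' fold changes and adjusted p-values were used as deposited, at a threshold of 0.05. All gene values in the report are the authors'.

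To give each fold change an error, the Benjamini-Hochberg adjustment was undone over the 14231 genes with an adjusted p. This returns the raw p where an adjusted value occurs once (655 genes) and an upper limit of it where several genes share a value (13576 genes). The implied p, read as a 2-sided Wald p, gives a signed z score, a standard error and a 95% interval. For genes with shared values the standard error is an upper limit. At an implied p under 0.05 there were 967 genes, 6.8% of those tested. The lowest mean with an adjusted p was 25.7 normalised reads, which marks the authors' filter on low values. The median log2 fold change of the tested genes was -0.03, and 45.1% lay above 0.

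Depth was recovered from genes with few reads. Their means are multiples of the value of 1 read in a library, and 4 such steps occur, 2 with a negative and 2 with a positive fold change. At a tolerance of 1e-06, 6669 of the 6669 genes with a mean above 0 and under 1 were whole-read combinations of the steps. The steps give each library's size factor, its depth relative to the other libraries in the authors' scaling. They were not tied to replicate numbers, and total reads per library are unknown. Intervals come from the authors' test and include the spread between libraries. The thinly covered MIR193BHG had an implied standard error of 0.497, against 0.171 for MIR22HG. Width did not follow coverage alone. The abundant RPS16, chosen after its value was seen, had an implied standard error of up to 0.770 at a mean of 5836 normalised reads in the authors' deposited table.

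Gene coordinates and hairpin positions came from GENCODE release 29 on the same build. Gene IDs without their version matched for 57388 of the 58037 rows, 53647 of them with the same version. A gene was called a hairpin host where an annotated microRNA gene lay within its extent on the same strand.

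Before the data were examined, 26 gene lists were fixed, of which 25 had at least 5 tested members. Each was tested with camera on the signed z scores in its preranked form (limma 3.58.1, R 4.3.3) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. A correlation cannot be estimated without values for each library. A preset of 0.05 was used in its place, and 4 of the 5 calls held with it. List medians were also set against 10000 random lists matched on mean expression in 20 bins, with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. A permutation p given with random lists is the 2-sided share of those lists with a value as far out. No library labels were permuted. In simulated tables of 14231 genes, undoing the adjustment returned untied p-values exactly, as it must by construction. On the z scores so recovered, tied ones included, camera found 3 of 3 lists shifted by 1 in z and 0 of 3 shifted by 0.5. The random-list test passed 2 of 100 unshifted simulated lists of 50 genes, 25 of 100 shifted by 0.05 on the log2 scale and 73 of 100 shifted by 0.1. The simulated lists held genes taken at random, so these rates do not carry over to lists whose members vary together. Random-list p-values likewise take no account of members that vary together.

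Named genes followed a rule fixed beforehand. It takes DROSHA and DGCR8, and up to 12 higher and 12 lower genes of largest fold change among called genes whose mean is at or above the median of the tested genes, clone names excluded. It also takes up to 4 members of each list with the smallest p and the 5 hairpin or host transcripts with the smallest p. Its further condition, that both knockdown libraries lie on one side of both control libraries, could not be applied. Genes named outside the rule are stated as such, and 1 gene that the rule takes is not reported here.

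Alternatives were other thresholds, a higher minimum mean, protein-coding genes only, re-centred fold changes and other forms of the set test. Other normalisations, other count tools, other filters before the fit, the replicate number as a block and leaving out each library were planned but need values per library.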

Results

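Knockdown of DROSHA in K562 cells, a human erythroleukaemia line of myeloid origin, went with higher levels of a small group of transcripts, among them many that carry microRNA hairpins. DROSHA is the nuclear ribonuclease that, with its partner DGCR8, crops primary microRNA transcripts. At an adjusted p under 0.05, 47 genes were higher and 3 were lower in the knockdown cells in the authors' deposited table. Of the 47 higher genes, 15 held an annotated microRNA hairpin on their own strand. The cells had been transduced with a CRISPR lentivirus that targeted DROSHA or with a non-specific one and selected with puromycin, and total RNA was sequenced from 2 control and 2 knockdown libraries.

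The deposited values were 1 table for the whole comparison. It gave a mean normalised read count over the 4 libraries, a log2 fold change and an adjusted p for each gene, and no value for a single library. Of 58037 genes listed, 27380 had a mean of 0 and 14231 had an adjusted p, of which 11608 were protein-coding. The means summed to 50129936 normalised reads, and the mitochondrial ribosomal RNA MT-RNR2, singled out after its value was seen, alone took 21.5% of that sum in the authors' deposited table. The depth of each library is known only as a relative size factor. These were 1.23 and 0.918 for the libraries on the control side and 1.09 and 0.813 for those on the knockdown side, so the deepest library was under 2-fold deeper than the shallowest. The labels do not say whether the replicates were separate cultures, so the p-values measure the spread between these libraries, which may be technical. The direction of the fold change was read from the targeted gene, so its sign is no check of the labels or of the knockdown, and which size factors belong to the control side rests on the same reading. DROSHA, on chromosome 5 from 31400497 to 31532196 on the minus strand in hg38, had a log2 fold change of -1.15 (implied standard error 0.135, adjusted p = 8.1e-14) at a mean of 4422 normalised reads in the authors' deposited table. The interval implied by that p ran from -1.41 to -0.88.

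The comparison of the cell populations asks which RNAs differ in level when DROSHA is reduced. The transcript with the smallest adjusted p in the authors' deposited table was MIR22HG, the non-coding host of the miR-22 hairpin, with a log2 fold change of 2.57 (implied standard error 0.171, adjusted p = 3.8e-47). DGCR8, which binds DROSHA and itself carries the hairpins MIR3618 and MIR1306 in an exon, came next at 1.72 (implied standard error 0.147, adjusted p = 1.2e-27) in the authors' deposited table. It lies on chromosome 22 from 20080232 to 20111877. Of the 10 genes with the smallest adjusted p, 6 held a hairpin. The plot of fold change against mean expression shows these transcripts at the upper edge of the distribution.

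**Figure D1:**
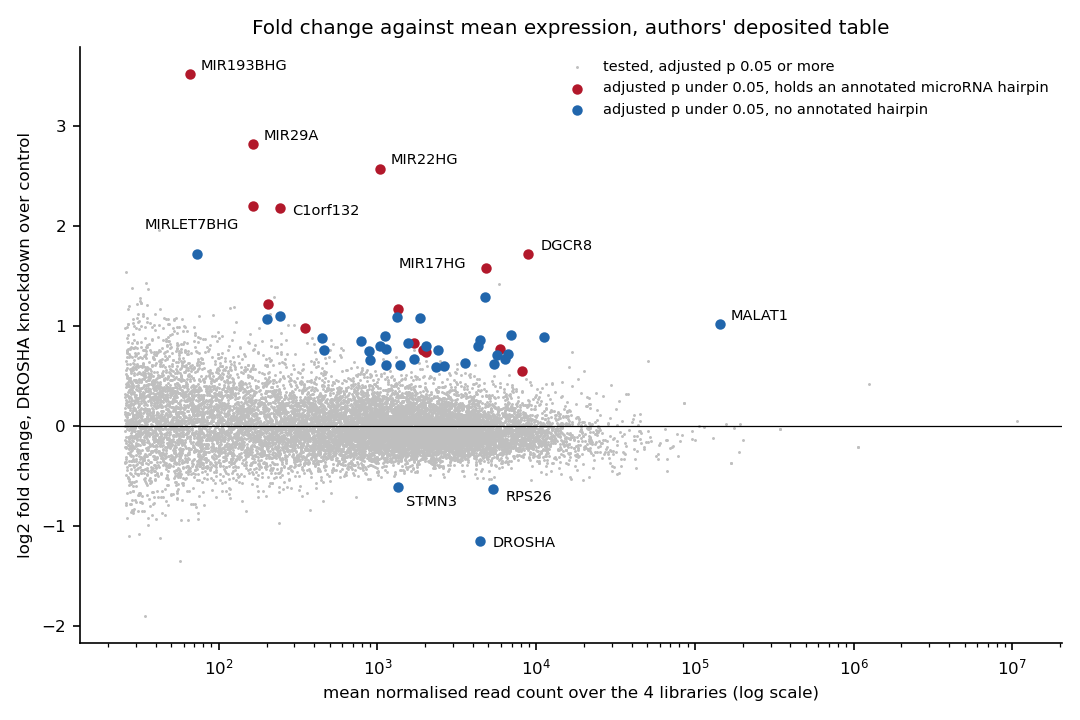
Log2 fold change of DROSHA knockdown over control against the mean normalised read count over 4 libraries (log scale), 1 point per tested gene. Grey points had an adjusted p of 0.05 or more, red points passed and hold an annotated microRNA hairpin (15 genes), and blue points passed without one. MIR193BHG at 3.52, MIR29A at 2.82 and MIR22HG at 2.57 lie highest, and DROSHA at -1.15 is the lowest of the 3 lower genes.

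Host transcripts of microRNAs formed the most strongly shifted of the gene lists. Of 17 tested host transcripts, 6 were higher, 0 were lower and 11 did not pass, with a median log2 fold change of 0.74 (camera adjusted p = 4.2e-27). The rank version of camera, less swayed by extreme members, gave an adjusted p of 0.0097. With ranks of the fold change it was 0.0026. Adjusted over the list alone, 7 were higher. MIR17HG, which hosts the miR-17/92 cluster, rose by 1.58 on the log2 scale (adjusted p = 1.1e-13), C1orf132, which holds MIR29B2 and MIR29C, by 2.18 (adjusted p = 2.2e-12), and MIR193BHG by 3.52 (adjusted p = 2.1e-09) in the authors' deposited table. MIR193BHG had a mean of only 65.9 normalised reads and an implied interval from 2.54 to 4.49. The 2 remaining called members, chosen here after their values were seen, were MIRLET7BHG at 2.19 and DLEU2, which hosts MIR15A and MIR16-1, at 0.76 in the authors' deposited table. Members that did not pass included H19 at -0.27 and MIR4435-2HG at -0.09 in the authors' deposited table, also chosen after their values were seen. The host H19 had an adjusted p of 0.934.

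Several rows carry the symbol of a hairpin but a longer non-coding biotype. Of 41 such rows, 13 were tested and 4 were higher. The long intergenic transcript listed as MIR29A, on chromosome 7 from 130876809 to 130913310 on the minus strand, had a log2 fold change of 2.82 (adjusted p = 3.7e-13) in the authors' deposited table and holds MIR29B1. The other 3, chosen after their values were seen, were the rows listed as MIR24-2 at 1.22, MIR4732 at 0.98 and MIR223 at 0.83 in the authors' deposited table. The MIR4732 row holds the erythroid hairpins MIR144 and MIR451A. The annotated hairpin genes themselves were scarcely covered by these libraries. Of 1558, 432 had a mean above 0, 16 were tested and 0 passed DESeq2's test in the authors' deposited table, with 0 at an implied unadjusted p under 0.05. Reads over a hairpin cannot be told from reads of the transcript around it, and mature microRNAs are not measured by this library type.

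The microRNA pathway list as a whole did not pass camera (adjusted p = 0.382), while its median lay above random lists matched on expression (-0.14 to 0.01, adjusted permutation p = 0.035). Of its 25 tested members, DGCR8 was higher, DROSHA was lower and 23 did not pass, and the median log2 fold change was 0.04. TNRC6A, a partner of the Argonaute proteins, was listed at 0.50 (adjusted p = 0.135) and DICER1, chosen after its value was seen, at 0.10 (adjusted p = 0.958) in the authors' deposited table. Adjusted over the list alone, 2 members were higher, the second being TNRC6A, and 1 was lower.

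Of the higher genes, 32 held no annotated hairpin on their strand. The nuclear non-coding RNA MALAT1 rose by 1.02 on the log2 scale (implied standard error 0.131, adjusted p = 1.4e-11), the selenophosphate synthetase SEPHS2 by 1.08 (adjusted p = 4.5e-10) and MRPL12, a mitochondrial ribosomal protein, by 1.08 (adjusted p = 1.1e-06) in the authors' deposited table. Smaller rises were listed for BANF1, a chromatin-binding protein, at 0.90, MAT2A, which makes S-adenosylmethionine, at 0.89, and the RNA-binding protein TARDBP at 0.86 in the authors' deposited table. NSRP1, a splicing regulator whose annotated extent holds MIR423, rose by 1.17 (adjusted p = 5.8e-05) in the authors' deposited table. A short row inside MALAT1 and a clone-named row that overlaps TARDBP can share reads with those genes, and without them 45 genes were higher. Besides DROSHA, the lower genes were the ribosomal protein gene RPS26 at -0.62 (adjusted p = 0.0069) and the stathmin gene STMN3 at -0.61 (adjusted p = 0.029) in the authors' deposited table. RPS26 has near-identical processed copies in the genome, so its count is uncertain.

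**Figure D2:**
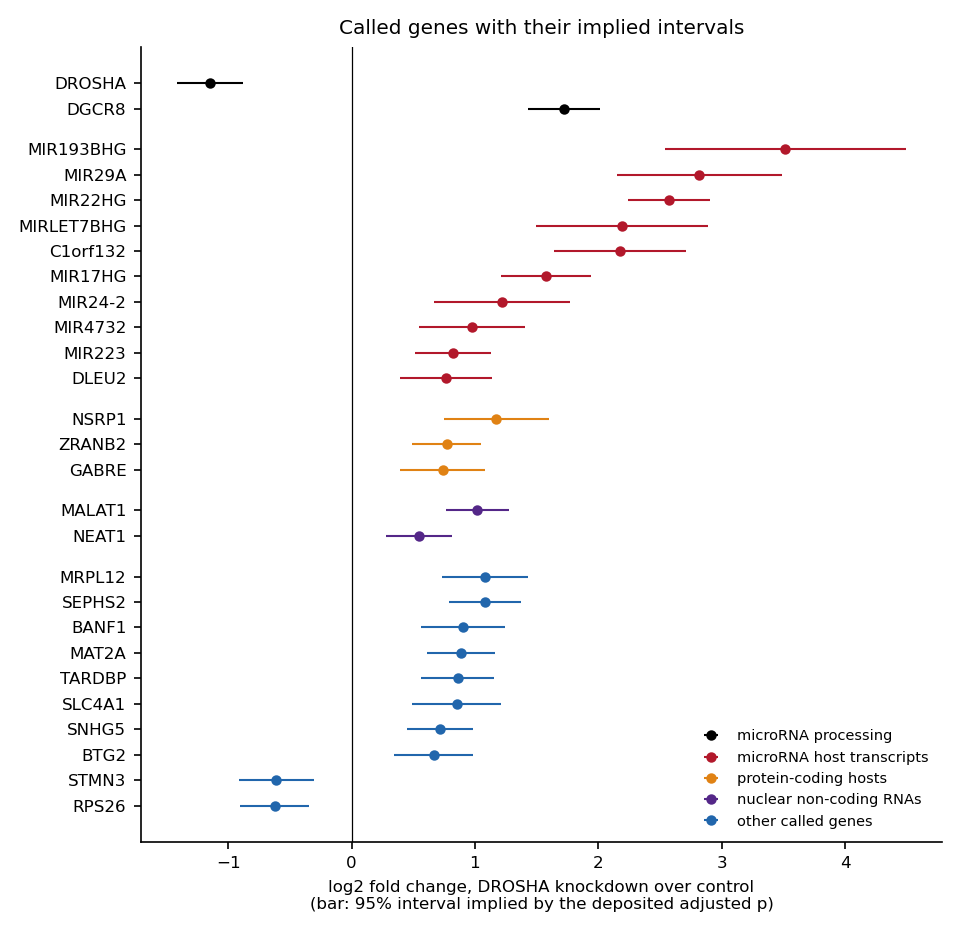
Log2 fold change of DROSHA knockdown over control for 27 called genes, with the 95% interval that the deposited adjusted p implies (bar). DROSHA, STMN3 and RPS26 lie below 0, and the 10 hosts drawn in red span 0.76 (DLEU2) to 3.52 (MIR193BHG). The protein-coding hosts ZRANB2 and GABRE lie at 0.77 and 0.74, and NEAT1, drawn with the nuclear RNAs, also holds a hairpin and lies at 0.55, these 3 chosen after their values were seen.

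Replication-dependent histone mRNAs, which lack poly(A) tails, were lower as a group although none was called singly. Of 47 tested, 44 had a log2 fold change below 0, the median was -0.34 and the camera adjusted p was 6.3e-22. Over all genes 0 passed, while adjusted over the list alone 27 were lower. HIST1H2AK at -0.48 (adjusted p = 0.099) and HIST1H3J at -0.51 (adjusted p = 0.102) came closest in the authors' deposited table. Histone genes are near-identical copies of one another, so the value of a single gene is uncertain.

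Ribosomal protein mRNAs were slightly lower as groups. Of 79 cytosolic ribosomal protein genes, 60 lay below 0 with a median of -0.17 (camera adjusted p = 6.9e-06), and RPS26 was the 1 called member, also when adjusted over the list alone. RPS3A was listed at -0.40 and RPLP0 at -0.33 with adjusted p of 0.359 and 0.428 in the authors' deposited table. Of 79 mitochondrial ribosomal protein genes, 67 lay below 0 with a median of -0.18 (camera adjusted p = 1.2e-05), while the 1 called member over all genes and over the list alone, MRPL12, was higher. The nuclear-encoded oxidative phosphorylation list also passed, with a median of -0.11 over 44 members and a camera adjusted p of 0.021. None of its members was called, over all genes or adjusted over the list alone, and COX6B1 at -0.37 (adjusted p = 0.321) had the smallest p in the authors' deposited table. That call was lost at a higher preset correlation of 0.05 (adjusted p = 0.27). Across 11377 protein-coding genes the fold change increased with the length of the principal transcript (Spearman's rho 0.169, genes not being independent). Random lists matched on expression and on that length had medians from -0.19 to -0.13 for the cytosolic list, a range that includes its own, and from -0.15 to -0.06 for the mitochondrial list, which lay below it. For the oxidative phosphorylation list they ran from -0.19 to -0.07, a range that includes its own median (2-sided permutation p = 0.457).

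**Figure D3:**
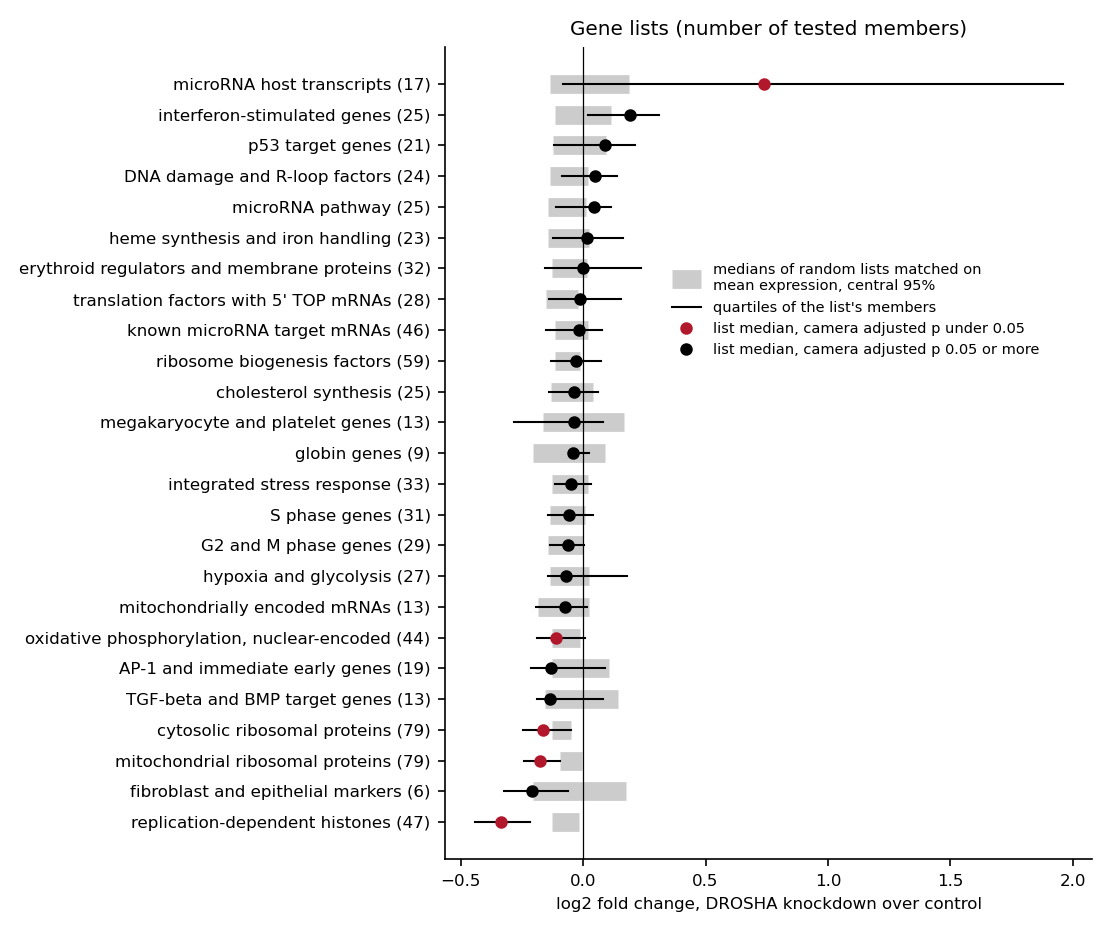
Median log2 fold change of each of 25 gene lists (points), with the quartiles of its members (lines) and the central 95% of medians of 10000 random lists matched on mean expression (grey bars). Red points passed camera at an adjusted p under 0.05. The microRNA host transcripts lie highest at 0.74 and the replication-dependent histones lowest at -0.34.

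Genes of the erythroid programme did not pass the set test as groups. The heme and iron list of 23 members had a median of 0.02 (camera adjusted p = 0.107). SLC25A37, the mitochondrial iron importer, passed when adjusted over the list alone, at 0.44 with an adjusted p of 0.134 over all genes in the authors' deposited table. SLC4A1, the band 3 anion exchanger, rose by 0.85 (adjusted p = 0.0023) in the authors' deposited table and was the 1 called member of 32 erythroid regulator and membrane genes, over all genes and over the list alone. That list had a median of -0.0015 and a camera adjusted p of 0.56. Of 9 globin genes 0 were called (median -0.04, camera adjusted p = 0.56), with HBG2 at -0.05 and HBD at -0.34 in the authors' deposited table. HBG2 and HBA2 have near-identical neighbours and are uncertain. The megakaryocyte list (13 members, median -0.04, camera adjusted p = 0.649) had 0 called members.

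Interferon-stimulated genes had 20 of 25 members above 0 and a median of 0.19, and 0 were called. Their camera adjusted p was 0.156, and 0.464 at a preset correlation of 0.05. The list passed with the rank version of the test (adjusted p = 0.045), with ranks of the fold change (adjusted p = 0.0094) and against random lists (adjusted permutation p = 0.012). BST2 had the smallest p, with 0.50 and an adjusted p of 0.361 in the authors' deposited table. BTG2, a p53-responsive antiproliferative gene, rose by 0.67 (adjusted p = 0.016) in the authors' deposited table and was the 1 called member of 21 p53 targets, over all genes and over the list alone (median 0.09, camera adjusted p = 0.42). SNHG5, a snoRNA host, rose by 0.72 (adjusted p = 1.1e-04) in the authors' deposited table. It was the 1 called member of 28 translation factor and 5′ TOP transcripts, over all genes and over the list alone (median -0.01, camera adjusted p = 0.564). Known microRNA target mRNAs did not pass, with 0 of 46 called, a median of -0.02 and a camera adjusted p of 0.706. PDCD4, a target of miR-21, stood at 0.47 (adjusted p = 0.512) and CCNE1, a target of the miR-16 family, at -0.48 (adjusted p = 0.196) in the authors' deposited table.

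The remaining lists held 0 called members over all genes and did not pass camera. Medians were -0.05 for the integrated stress response (adjusted p = 0.808), -0.06 for S phase genes (adjusted p = 0.564) and -0.06 for G2 and M phase genes (adjusted p = 0.353). They were -0.03 for ribosome biogenesis factors (adjusted p = 0.802), 0.05 for DNA damage and R-loop factors (adjusted p = 0.353, and 0.038 against random lists), -0.04 for cholesterol synthesis (adjusted p = 0.465) and -0.07 for hypoxia and glycolysis genes (adjusted p = 0.625). Mitochondrially encoded mRNAs had a median of -0.08 (adjusted p = 0.388), AP-1 and immediate early genes -0.13 (adjusted p = 0.649), and TGF-beta and BMP targets -0.13 (adjusted p = 0.465). Adjusted over its list alone, 1 gene passed in each of 4 of these lists. NOB1 at 0.51 and RPA1 at 0.53 were higher, and PGAM1 at -0.60 and MT-ND5 at -0.54 were lower, in the authors' deposited table. The markers of other cell types gave 0 calls, with a median of -0.21 over 6 fibroblast and epithelial markers (adjusted p = 0.353) and of -0.26 over 4 blood lineage markers, too few for a set test. The ribosome biogenesis list had a median below 0 but a mean of 0.01 and a test direction upward, as did the 5′ TOP list with a mean of 0.04 and the erythroid regulators with a mean of 0.03.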

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

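Alternatives other than the thresholds of 0.01 and of a log2 fold change of 1 were chosen after the data were seen. DROSHA stayed past the threshold under all 7 settings run, with a log2 fold change of -1.15 to -1.12 and an adjusted p of at most 3.2e-13. All settings but re-centring reuse the deposited fold change, so no direction could change in them. With so small a p, DROSHA could hardly be lost either, so this is little check of the result. The count of higher genes, 47, fell to 16 when a log2 fold change of at least 1 was also required, to 24 with Bonferroni adjustment and to 30 among protein-coding genes adjusted again, against 32 protein-coding genes in the whole table. It ran from 33 at an adjusted p under 0.01 to 58 under 0.1 in the other settings. The count of lower genes, 3, became 1 with the fold requirement and 1 with Bonferroni adjustment, in both cases by construction, and 7 at an adjusted p under 0.1. Lists past the threshold numbered 4 to 7 against 5, and the microRNA host, histone and both ribosomal protein lists were called in each alternative. Oxidative phosphorylation was lost at a preset correlation of 0.05, with ranks of the fold change (adjusted p = 0.07) and against random lists (adjusted p = 0.238). Interferon-stimulated genes were gained in 3 of the 4 other set tests, all but the higher preset correlation. The microRNA pathway and the DNA damage lists were gained against random lists. Of the named genes run again, those named outside the rule included, only ZSWIM4 changed sign, to 0.0241 with re-centred fold changes. Re-centring was the only setting that could change a sign, and ZSWIM4 was called in neither case. Hairpin genes gave 0 calls throughout.

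No paired analysis was possible because the table holds no value per library. For the same reason other normalisations, edgeR, limma-voom, a renewed DESeq2 fit, other filters before the fit, other pseudocounts, small structural RNAs left out of the library size and leaving out each library were not run. Whether 1 library decides a call is thus unknown. Low coverage limits the hairpin genes, since 416 of the 432 with a mean above 0 lay below the authors' filter. Whether depth or the library type sets that coverage was not tested.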

Other observations

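The tests on overlapping genes, on the share of nuclear RNA, long nuclear RNA included, and on unspliced RNA, the comparison of both ribosomal protein lists and the match on principal transcript length were chosen after the values they measure, or closely related ones, were seen. Host classes, the lists of splicing and nuclear RNAs and the site test were drawn up after the called genes were known.

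The rise of host transcripts depended on the class of host. Of 73 tested non-coding genes with an annotated hairpin on their strand, 11 were higher and 0 lower, with a median log2 fold change of 0.22 (random lists matched on expression -0.07 to 0.07). Those with the hairpin in an exon had a median of 0.36 over 25 genes, of which 9 were higher, and those with it in an intron 0.14 over 48 genes, of which 2 were higher. Of 138 protein-coding genes with a hairpin in an exon, 3 were higher, namely DGCR8, NSRP1 and GABRE, which holds MIR224 and MIR452 and was named after its value was seen. Of 525 with hairpins in introns only, 1 was higher, ZRANB2 with MIR186, also named after its value was seen, and their median was -0.05. Together hosts were called higher in 15 of 736 genes against 32 of 13489 other tested genes (2-sided Fisher's exact test p = 7.1e-09).

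Small nucleolar and intronic RNAs also lay high. The median was 0.27 over 71 snoRNA genes (matched random lists -0.03 to 0.17) and 0.01 over 36 snRNA genes (-0.09 to 0.12). Hairpin genes below the authors' filter had a fold change above 0 in 279 of 416 cases, or 67.1%, against a median of 58.2% in random lists matched on expression (2-sided permutation p = 4e-04). The 16 tested ones had a median of 0.37, above the random range of -0.13 to 0.31 (2-sided permutation p = 0.0128 over random lists). Called genes with no hairpin, named here after their values were seen, included LUC7L3 at 0.80, PNISR at 0.62 and SNRPA1 at 0.83 in the authors' deposited table. The endoplasmic reticulum chaperone HSPA5, also named after its value was seen, rose by 0.71 in the authors' deposited table, while the integrated stress response list did not pass.

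Loss of hairpin cropping is a candidate explanation for the rise of non-coding hosts. Their median exceeded that of protein-coding hosts with intronic hairpins by 0.26 (permutation p = 1e-05, the smallest that the permutations can give). The 2 classes differ in biotype too, which was not matched. With hosts included, the median was 0.06 over 565 lincRNA genes, 0.04 over 572 antisense genes and 0.27 over 130 sense-intronic transcripts. A part of the difference may thus go with biotype. For protein-coding hosts with hairpins in introns, the median of -0.046 lay within its random range of -0.06 to -0.02 and its bootstrap interval ended at -0.03. That argues against a rise of this class as a whole. For reads shared with overlapping genes, 10 tested overlapping rows without a hairpin, at 4 of the hosts, had a median of 0.053 (bootstrap interval -0.13 to 0.36). The called hosts had 1.22. Most of these rows lie at DLEU2 and NEAT1, which rose by only 0.76 and 0.55, and several are parts of the same gene, so the interval is too narrow. The same-strand rows within NEAT1 lay at 0.35, 0.79 and 0.43. The sizes of the overlapping genes argue against shared reads more directly. In 11 of the 15 called hosts every overlapping gene lay under 10% of the host's mean. At the other 4, the most abundant overlapping gene reached 79.6% of the mean of MIR22HG (WDR81, log2 fold change -0.10), 78.2% of DLEU2 (DLEU1, 0.11), 60.3% of DGCR8 (TRMT2A, 0.12) and 26.5% of MIR24-2 (ZSWIM4, -0.0033) in the authors' deposited table. These 4 overlapping genes were named after their values were seen. Release from cropping may therefore be the explanation, as a hypothesis tested on the data it came from, and a change in transcription of the hosts was not tested.

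Cytosolic ribosomal protein mRNAs were lower, and transcript length may account for this. Matched on expression and on the union of annotated exons, random lists lay higher than the list (2-sided permutation p = 0.0092). That union is a poor measure here, with a median of 3109 bases for these genes against 802 for their principal transcripts. Matched on principal length, the list lay inside the random range (2-sided permutation p = 0.78), so length stays open. Those random lists could draw mitochondrial ribosomal protein, oxidative phosphorylation and histone genes, which also had medians below 0. Such genes may lower the random range, so the match cannot show that length absorbs the shift. A change confined to cytosolic ribosomal proteins is argued against, because the mitochondrial ones had a median of -0.179, below random lists matched on expression and principal length (2-sided permutation p = 6e-04). Whether both lists fell for the same reason stays open. Histones also lay below such lists (2-sided permutation p = 2e-04), so length alone leaves part of the mitochondrial and histone shifts.

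MALAT1 and NEAT1 were higher, at 1.02 and 0.55 in the authors' deposited table, and NEAT1, chosen after its value was seen, holds MIR612 and is counted among the 15 called hosts too. A larger share of all nuclear RNA would raise abundant nuclear non-coding RNAs alike. Their 16 rows had a median of -0.116 (bootstrap interval -0.27 to 0.05), which argues against a rise of these RNAs as large as MALAT1's. Some rows are second entries of the same gene, so the interval is too narrow. Small nucleolar RNAs lay higher, with a median of 0.27 over 71 genes (matched random lists -0.03 to 0.17). A smaller rise in part of the nuclear RNA thus stays open. A larger share of long nuclear RNA stays open. A list of 13 other long non-coding RNAs taken as nuclear-retained, 10 of them above 0, had a median of 0.074 with a wide bootstrap interval of 0.03 to 0.60 (camera adjusted p = 8.3e-04 over 3 added lists, random-list permutation p = 0.115). That list tests the point poorly. It includes NORAD and OIP5-AS1, which are not confined to the nucleus, and MIAT, which is also in the microRNA host list. These were named after their values were seen. More unspliced RNA would raise sense-intronic transcripts, and 130 of them had a median of 0.269 (matched random lists -0.01 to 0.12). That test covers other transcripts only, so it cannot decide whether unspliced RNA has any part in the rise of MALAT1 and NEAT1. Splicing factor and SR-protein mRNAs, called genes left out, moved with them, with a median of 0.149 over 63 genes and 49 above 0 (random lists -0.12 to -0.03, 2-sided permutation p = 2e-04, the smallest that these lists can give).

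Loss of microRNA repression was tested on 18 microRNA families in the 3′ UTRs of 11147 protein-coding genes. The median log2 shift of mRNAs with an 8-mer site, corrected for 3′ UTR length, was set against 8-mers of the same bases in another order. The median over families was 0.0056 above the controls, 12 of 18 lay above them, and 3 passed at an adjusted p of 0.041. These were miR-18, miR-19 and miR-92/25/32, with shifts of 0.065, 0.051 and 0.050, each above all of its 164, 145 and 403 control 8-mers, so that each raw p is the smallest the controls can give. A first run with fewer control 8-mers could not reach the threshold, and their number was raised for that reason. It still ran from 56 for miR-23 to 403 for miR-92/25/32. A family with few controls, such as miR-23 or miR-29 with 69, could not have joined the 3 passing families singly. All 3 families have members in the cluster within MIR17HG, while the miR-17/20 family, also in it, lay 0.012 above its controls (adjusted p = 0.351). Let-7 sites lay 0.016 below theirs. In simulated shuffles of these genes a shift of 0.05 in 3 families was found in 3 of 3. That result does not cover the families with few controls. A general release of microRNA targets thus stays open, since most families did not pass and the median was above 0.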
